A study of Arabidopsis thaliana with 9 samples.

How the data were processed

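Poly(A) RNA from whole seedlings of Arabidopsis thaliana was measured in 9 libraries sequenced on the BGISEQ-500 platform. The seeds were stratified for 2 days at 4 °C, exposed to a 2 h pulse of white light and kept in darkness for 22 h. Growth then went on at 22 °C for 3 days under red light, whose fluence rate was 80 µmol per square metre and second, so that the seedlings were 4 days old at harvest. The 3 genotypes were wild type (WT, Col-0), the bbx20 bbx21 bbx22 triple mutant (bbx202122) and hy5, with 3 libraries each. Nothing in the labels says that the replicates were separate cultures, so the p-values measure the spread between these samples, part of which may be technical. The labels state an ecotype for WT and not for the mutants, and the mutant alleles are not given in the sources used here.

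Per the submitters' notes, the authors used HISAT (version not given in the sources used here), Bowtie2 2.2.5, RSEM 1.2.12 and the genome build TAIR10, with the order and roles not stated. The deposited files give, per library and gene, the expected counts estimated by RSEM, which are unscaled and partly fractional. They also give the deposited FPKM values, normalised by the authors to transcript length and library size. Each file lists the genes with an FPKM of at least 0.01, and a gene missing from a file was set to 0 in that library. Over the 9 files 24640 genes were listed, 21412 of them in every file. Gene identifiers of 24436 genes matched a TAIR10.1 annotation table by identifier, and the 204 others were all organelle genes. Coordinates are those of TAIR10.1.

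The expected counts were rounded to whole numbers and fitted with edgeR 4.0.16 in R 4.3.3, with 1 mean per genotype over all 9 libraries, TMM scaling and the filterByExpr filter by genotype, which left 20751 genes. The fit had 6 residual degrees of freedom and a common dispersion of 0.0041. Each of the 3 comparisons (bbx202122 against WT, hy5 against WT, and bbx202122 against hy5) was tested with the quasi-likelihood F test, two-sided, and p-values were adjusted by Benjamini-Hochberg. A gene is called, or said to have risen or fallen, at an adjusted p under 0.05. Levels are counts per 1e6 counts (CPM) on TMM-scaled library sizes, given as mean ± SD over 3 libraries. Log2 fold changes are the fitted ones ± SE, with the SE taken as the fold change divided by the root of F, and they compare 3 libraries with 3. Folds against a genotype with 0 counts are lower bounds, computed with 3 counts over the group, and for genes with 1 to 3 counts in a genotype the ratio is given with its 95% exact binomial interval. Such bounds and intervals cover counting error only.

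The library totals, 21.6 to 22.8 in units of 1e6 expected counts, put 3 counts in a single library at 0.132 to 0.139 CPM. Simulated data of 20520 genes held known changes in 57 to 142 genes per fold and comparison, and at least 20120 genes were unchanged. There the test recovered 73.1 to 83.1% of 1.5-fold changes, 93 to 97.5% of 2-fold changes and 98.5 to 99.3% of 4-fold changes. Of its calls 6.3 to 7.1% were false. These shares hold for data with few changed genes, unlike the data here.

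Before the data were examined, 31 lists with 439 genes were fixed from pathway, regulator and tissue knowledge, and 437 of these genes were in the files. For each list the called members were counted with p-values adjusted over all genes and adjusted over the list alone. Apart from the mutated genes, the other 30 lists were tested as sets with camera in limma 3.58.1, with a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over lists. The function fry was used to test whether a list's genes moved, on balance, one way. On simulated data a list shifted by 0.6 on the log2 scale was found, and 0 of 29 other lists were called. Genes were drawn independently there, so this does not check false calls of lists with correlated genes. In the measured data the estimated correlation reached 0.692 (anthocyanin list, hy5 against WT). For the motif test below, a set of uncalled genes gave a ratio of 1.02 unchanged and 3.91 with the motif added to 30%. The comparisons, their tests and the rule for named genes were also fixed before the data were examined. The tests of gene-poor regions and sequence background, and the motif counts of genes called in a single mutant, were chosen after the results were seen.

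Named genes are the 4 mutated genes; for each comparison, the 5 largest increases and the 5 largest decreases among called genes with a mean of at least 5 CPM and no overlap between the genotypes' libraries; up to 4 called members with the smallest adjusted p per list (for a list with fewer than 2 called members, its 2 with the smallest adjusted p, given as values); and, of the genes called in both mutants, the 5 largest mean changes in each direction and the 5 with the smallest adjusted p among those called in opposite directions. Genes expressed in a single genotype were singled out after their values were seen.

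The overlap of the mutants was compared with that of independent lists and with 20 simulated data sets in which unchanged mutants shared the WT libraries. Upstream sequences of 500 bp were searched for the G-box motif CACGTG, and sets were compared with 1000 draws of uncalled genes matched on expression and GC content. Alternatives were DESeq2 1.42.0, other scalings (RLE size factors and library size only), no low-count filter and a stricter one, a replicate block, fits of 6 libraries, limma on log2 FPKM with 2 pseudocounts and with and without a filter, a minimum 2-fold change, leaving out organelle genes, a stricter threshold for the overlap, and leaving out each library. An alternative without genes under a mean of 10 counts in any genotype was chosen after seeing the data. Motif, sequence and position analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. Raw reads were not used here.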

Results

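Transcript levels were measured by RNA sequencing in whole seedlings of WT, the bbx202122 triple mutant and hy5 after 3 days in red light, with 3 libraries per genotype. HY5 is a bZIP transcription factor that promotes seedling development in light, and BBX20, BBX21 and BBX22 are B-box zinc finger proteins that act with it. In units of 1e6 expected counts, library totals were 22.0, 21.6 and 22.4 for WT replicates 1 to 3, 22.1, 22.2 and 22.8 for bbx202122, and 21.7, 21.9 and 21.7 for hy5. RBCS1A, which encodes a small subunit of Rubisco, was the most abundant transcript in 8 of the 9 libraries. The first principal component held 61.9% of the variance and placed bbx202122 (-17.17 to -16.61) between WT (-39.88 to -32.58) and hy5 (50.66 to 55.16). The second held 13.6% and set bbx202122 (-24.39 to -23.61) apart from both WT (17.87 to 19.73) and hy5 (2.49 to 7.46).

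The mutated genes were read first in every library. BBX22 (AT1G78600; TAIR10.1 chromosome 1, 29566863 to 29568931) fell from 28.9 ± 0.37 CPM in WT to 2.70 ± 0.27 CPM in bbx202122 (SD, n = 3 each), with 650, 638 and 636 counts in the WT libraries and 67, 60 and 57 in the bbx202122 libraries. BBX21 (AT1G75540; chromosome 1, 28365824 to 28367738) fell from 101 ± 8.7 to 25.7 ± 1.1 CPM. BBX20 (AT4G39070; chromosome 4, 18204631 to 18206684) was at 4.57 ± 0.37 CPM in WT and 4.1 ± 0.29 CPM in bbx202122, a log2 fold change of -0.16 ± 0.13 (adjusted p = 0.48), so the transcript level does not show that mutation. HY5 (AT5G11260; chromosome 5, 3593335 to 3595073) fell from 16.8 ± 1.5 CPM in WT to 8.23 ± 1.5 CPM in hy5 (adjusted p = 6.3e-06), with 190, 194 and 138 counts left in the hy5 libraries.

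The mutated genes also changed in the other mutant. HY5 fell to 6.34 ± 0.47 CPM in bbx202122 (log2 fold change -1.40 ± 0.12, adjusted p = 3e-06), and BBX20 fell to 2.14 ± 0.27 CPM in hy5 (-1.09 ± 0.15, adjusted p = 3.3e-05). BBX21 rose to 137 ± 4.6 CPM in hy5 (0.45 ± 0.06, adjusted p = 5.2e-05), and BBX22 in hy5 was at 29.8 ± 1.1 CPM (0.05 ± 0.06, adjusted p = 0.6).

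**Figure D1:**
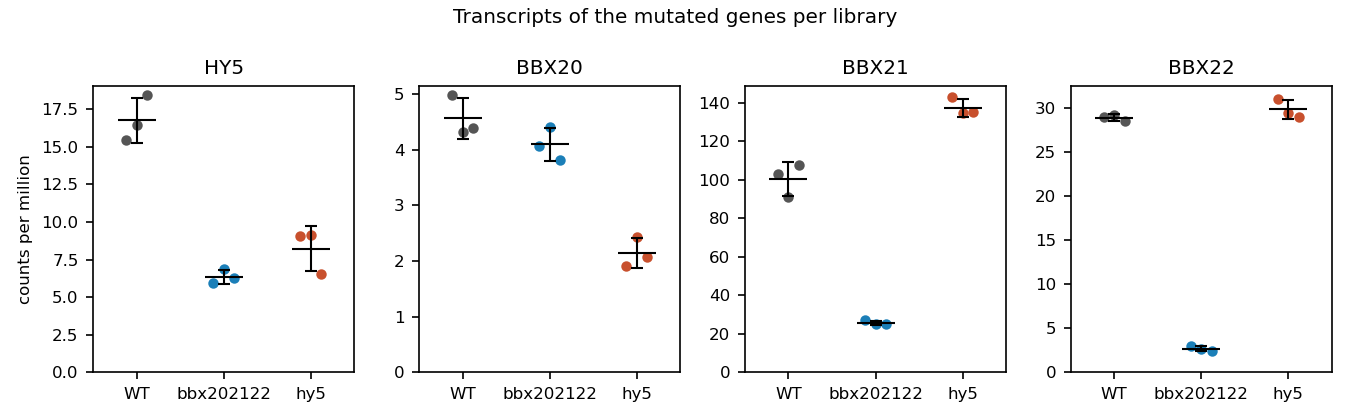
Levels of HY5, BBX20, BBX21 and BBX22 in CPM (vertical axes, each starting at 0) in WT, bbx202122 and hy5; points are libraries, lines the mean and SD of 3. BBX22 and BBX21 are low in all 3 bbx202122 libraries (means 2.70 and 25.7), while BBX20 is lowest in hy5 (mean 2.14) and HY5 is reduced in both mutants (means 6.34 and 8.23).

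The comparison of bbx202122 with WT asked which transcripts depend on the B-box proteins in red light. F3H (AT3G51240, flavanone 3-hydroxylase) fell from 28.6 ± 6.2 to 4.95 ± 0.58 CPM (log2 fold change -2.53 ± 0.20, adjusted p = 1.5e-06), and FLS1 (AT5G08640, flavonol synthase) fell from 22.8 ± 5.7 to 5.15 ± 0.20 CPM (-2.15 ± 0.15, adjusted p = 3.4e-07). CHS (AT5G13930, chalcone synthase, the entry enzyme) fell from 102 ± 20 to 39.9 ± 2.9 CPM, and MYB12 (AT2G47460), which encodes an activator of flavonol synthesis genes, fell by 2.56 on the log2 scale. Of 10 early flavonoid enzymes 7 fell and 3 were not called (9 fell when adjusted over the list alone), with a median of -0.77. Camera gave an adjusted p = 4.88e-17, and an adjusted p = 0.0863 with an estimated correlation. All 6 general phenylpropanoid enzymes fell (median -0.42, camera adjusted p = 1.73e-07; adjusted p = 0.0874 with an estimated correlation), among them PAL1 (-0.62 ± 0.09) and C4H (-0.36 ± 0.05). Of 9 anthocyanin genes 1 fell, SCPL10 (-0.97 ± 0.10), and 8 were not called, 5MAT being at -0.42 ± 0.26 (adjusted p = 0.3). The median of this list was -0.30 (camera, down, adjusted p = 0.0335; adjusted p = 0.519 with an estimated correlation). Of 11 flavonoid and anthocyanin regulators 3 fell, MYB12, EGL3 (-0.67 ± 0.12) and GL3 (-1.10 ± 0.24), and 1 rose, the repressor gene MYBL2 (0.75 ± 0.10). Counts adjusted over the list alone were the same for the last 3 lists.

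HYH (AT3G17609), the closest homologue of HY5, fell from 25.4 ± 2.0 to 11.1 ± 0.76 CPM (-1.20 ± 0.08, adjusted p = 3.4e-07). Of 10 UV-B and high-light response genes 7 fell and 2 rose (8 and 2 adjusted over the list alone), with ELIP2 at -1.44 ± 0.19, RUP2 at -1.24 ± 0.14 and SIG5 at -0.70 ± 0.07. Of 15 other B-box genes 7 fell and 1 rose, adjusted over the list alone too, with COL2 at -0.78 ± 0.08 and COL1 at -0.46 ± 0.07. Among 25 light signalling regulators 5 rose and 3 fell (6 and 4 adjusted over the list alone). The phytochrome-interacting factor genes PIL1 (0.90 ± 0.13), PIF3 (0.39 ± 0.08) and PIF4 (0.34 ± 0.06) rose. Of 22 clock genes 9 rose and 6 fell (10 and 7 adjusted over the list alone): the morning genes LHY (-1.25 ± 0.06) and CCA1 (-1.08 ± 0.07) fell and PRR7 (0.61 ± 0.05) rose.

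CGA1, a GATA factor of chloroplast development, fell (-0.80 ± 0.09), as did BCH2, a carotenoid hydroxylase (-0.80 ± 0.09). Called members numbered 2 lower of 6 chloroplast development regulators (4 adjusted over the list alone), 4 lower of 14 carotenoid genes (5), 2 higher and 8 lower of 24 chlorophyll and heme genes (2 and 11), 5 lower of 20 antenna genes (1 higher and 9 lower) and 9 lower of 26 photosystem, electron carrier and Rubisco genes (11), the counts adjusted over the list alone standing in brackets. CAO (-0.28 ± 0.06), LHCA5 (-0.25 ± 0.05) and PSBO2 (-0.31 ± 0.06) fell and PORB (0.41 ± 0.06) rose. In the same libraries 76 of 88 chloroplast-encoded transcripts rose, and these made up 0.433 ± 0.049% of the counts in bbx202122 against 0.227 ± 0.015% in WT. As the libraries were made from poly(A) RNA, this share does not show the level of chloroplast-encoded RNA as a whole. Single libraries moved some counts: called chlorophyll genes were 5 without WT replicate 3 and 6 without bbx202122 replicate 3; antenna genes 3 without WT replicate 3 or bbx202122 replicate 1; and photosystem genes 5, 3 and 4 without WT replicates 1, 2 and 3 and 4 without bbx202122 replicate 3.

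Of 17 genes for cell wall loosening 11 rose and 2 fell (11 and 3 adjusted over the list alone), with a median of 0.52. The xyloglucan endotransglucosylase gene XTH22 rose from 18.8 ± 4.3 to 49.1 ± 2.1 CPM (1.39 ± 0.11), XTH17 by 1.09 ± 0.10 and XTH18 by 1.03 ± 0.07 on the log2 scale. This list kept its camera call with both correlations (adjusted p = 5.75e-12 preset, adjusted p = 0.0416 with an estimated correlation). All 7 members of the sugar starvation and dark-inducible list rose, adjusted over the list alone too, among them DRM1 (0.80 ± 0.09), DIN10 (0.67 ± 0.09) and ASN1 (0.89 ± 0.15). The median of this list was 0.80 (camera adjusted p = 3.06e-09, and adjusted p = 0.087 with an estimated correlation). Of 32 auxin genes 10 rose (14 adjusted over the list alone; 6 without WT replicate 2 or without bbx202122 replicate 3) and 22 were not called, the risers including IAA19 (0.78 ± 0.09) and IAA6 (1.05 ± 0.15). GA3OX2, a gibberellin 3-oxidase gene, fell by 2.69 and GID1A, a gibberellin receptor gene, rose by 0.38 on the log2 scale. Of 21 gibberellin and brassinosteroid genes 4 rose and 3 fell (7 and 3 adjusted over the list alone), and their median (0.09) and mean (-0.03) differed in sign (camera adjusted p = 0.343). Of 14 glucosinolate genes 7 fell (1 rose and 8 fell adjusted over the list alone; 4 called without WT replicate 2), with CYP79B2 at -0.52 ± 0.08 and MAM3 at -0.87 ± 0.19.

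Outside these lists, the largest increases by the fixed rule were in ENODL1 (2.09 ± 0.17), AT4G37220 (1.79 ± 0.16), AT5G37950 (1.75 ± 0.14), scpl2 (1.72 ± 0.13) and ST2A (1.66 ± 0.10), a sulfotransferase gene of jasmonate metabolism, and all 5 also rose in hy5, although scpl2 shares 34.1% of its 50-base words with scpl1. The largest decreases by the same rule were, in order, in BBX22, F3H, GRP9 (-2.18 ± 0.14), FLS1 and TTL4 (AT3G58620), which fell from 29.0 ± 0.50 to 6.60 ± 0.80 CPM and was at 27.7 ± 1.5 CPM in hy5. In all, 3504 of 20751 genes were called, 1788 higher and 1716 lower, and 382 of them changed at least 2-fold. Camera called 18 of 30 lists, 4 up and 14 down, with the preset correlation; 1 kept its call with an estimated correlation, and the other 17 had an adjusted p of 0.0817 to 0.519. Without WT replicate 2 the count of called genes was 2236.

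The comparison of hy5 with WT asked which transcripts depend on HY5 in red light. The labels state no ecotype for hy5, so a differing sequence background cannot be told apart from the loss of HY5 in this comparison. Genes for glucosinolates, sulfur-rich defence compounds, fell in 13 of 14 cases. MAM1 (AT5G23010), which starts the elongation of the methionine chain, fell from 16.4 ± 4.6 to 0.409 ± 0.21 CPM (-5.30 ± 0.31, adjusted p = 7.5e-09). The next steps fell with it: IPMI2 (-5.01 ± 0.29), IPMI1 (-4.07 ± 0.25), IMD1 (-4.09 ± 0.25) and CYP83A1, which fell from 22.3 ± 6.2 to 0.757 ± 0.33 CPM (-4.87 ± 0.27). BCAT4 had 1 count in the hy5 libraries together, a ratio to WT of 0.00391 with a counting interval of 9.87e-05 to 0.022, and with CYP79F1 it was among 12 genes near 0 in hy5 alone. CYP79B3, of the indole branch, fell less (-1.15 ± 0.06). Of 14 glucosinolate genes 13 fell, adjusted over the list alone too; the median was -3.48, also with the 2 members at 3 counts or fewer set to their bounds. Camera gave an adjusted p = 1.96e-25, and an adjusted p = 0.0312 with an estimated correlation.

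DFR (AT5G42800, dihydroflavonol reductase) rose in hy5 from 7.93 ± 2.3 to 31.8 ± 7.7 CPM (2.00 ± 0.18, adjusted p = 6.6e-07), and LDOX from 6.55 ± 1.6 to 23.0 ± 7.1 CPM (1.81 ± 0.21). Of 9 anthocyanin genes 8 rose and 1, SCPL10, fell, adjusted over the list alone too (median 1.39, camera adjusted p = 9.15e-05; adjusted p = 0.425 with an estimated correlation). Of 10 early flavonoid enzymes F3'H (1.25 ± 0.23) and CHI (0.40 ± 0.08) rose, FLS1 (-1.67 ± 0.14) and F3H (-0.85 ± 0.17) fell, and 6 were not called, CHS being at 0.01 ± 0.13 (adjusted p = 0.94). The median was -0.06 (camera adjusted p = 0.559). All 6 phenylpropanoid enzymes fell (median -0.48, camera adjusted p = 0.00102; adjusted p = 0.296 with an estimated correlation). Of 11 regulators 4 rose, including MYB75, an anthocyanin activator gene (1.41 ± 0.20), and 4 fell, including MYB12 (-4.12 ± 0.28). For these lists the counts adjusted over the list alone were the same.

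HYH fell in hy5 from 25.4 ± 2.0 to 10.3 ± 0.48 CPM (adjusted p = 1.9e-08), LHY fell from 152 ± 13 to 48.0 ± 1.8 CPM (-1.67 ± 0.06) and CCA1 from 92.5 ± 8.5 to 37.6 ± 1.4 CPM, PRR7 rose by 0.75 ± 0.05, and PIL1 (1.17 ± 0.13) and PIF3 (0.88 ± 0.08) rose. Of 22 clock genes 13 rose and 6 fell (14 and 6 adjusted over the list alone), and of 25 light signalling regulators 8 rose and 3 fell (9 and 4). Of 10 UV-B and high-light genes 5 fell and 1 rose, with ELIP2 at -1.48 ± 0.19 and the photolyase gene PHR1 at -1.44 ± 0.13. Of 15 other B-box genes 5 fell and 2 rose, with COL2 at -1.02 ± 0.08 (4 called without WT replicate 2 or without hy5 replicate 3). Of 24 chlorophyll and heme genes 14 fell and 3 rose, with CHLI1 at -0.39 ± 0.06. Called members were 1 higher and 2 lower of 6 chloroplast development regulators, 1 higher and 4 lower of 14 carotenoid genes, 3 higher and 8 lower of 20 antenna genes and 1 higher and 7 lower of 26 photosystem genes. Counts adjusted over the list alone were the same for the lists in this paragraph other than clock and light signalling. With the preset correlation camera called no list in this paragraph (adjusted p = 0.0511 to 0.567). Over all tested genes, 39.5% were called in hy5. CGA1 (-1.07 ± 0.10) and BCH2 (-0.89 ± 0.09) fell. Called antenna genes were 6 without WT replicate 3 or hy5 replicates 1 or 2 and 7 without hy5 replicate 3. With library size as the only scaling 15 photosystem genes were called, and the medians of the carotenoid list (0.01) and of the other B-box list (0.00) both became -0.05. Of 88 chloroplast-encoded transcripts 8 rose and 1 fell, at 0.250 ± 0.072% of the counts (0.19 to 0.33% in single hy5 libraries).

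GPT2, a plastid glucose-6-phosphate transporter gene, rose from 3.09 ± 1.1 to 29.7 ± 3.9 CPM (3.27 ± 0.21). All 7 members of the sugar starvation and dark-inducible list, GPT2 among them, rose, adjusted over the list alone too. The median was 0.96 (camera adjusted p = 3.32e-08, and adjusted p = 0.175 with an estimated correlation). The list name does not show that each member, GPT2 included, responds to starvation. Of 17 cell wall loosening genes 11 rose and 1 fell (13 and 1 adjusted over the list alone), with XTH22 at 1.43 ± 0.11 and XTH30 at 1.13 ± 0.08. The camera call held with an estimated correlation (adjusted p = 5.27e-09 preset, adjusted p = 0.0419 estimated). Of 32 auxin genes 18 rose and 3 fell, adjusted over the list alone too (median 0.43, camera adjusted p = 9.15e-05; adjusted p = 0.295 with an estimated correlation), including IAA19 (1.04 ± 0.09) and GH3.5 (0.78 ± 0.09). Of 21 gibberellin and brassinosteroid genes 9 rose and 3 fell (9 and 4 adjusted over the list alone), with BR6OX2 at 0.56 ± 0.06 and GA3OX2 at -3.28 ± 0.33. The median (0.16) and the mean (-0.07) differed in sign (camera adjusted p = 0.429). Of 14 abscisic acid genes 7 rose, adjusted over the list alone too, and RD29A rose from 36.1 ± 4.9 to 103 ± 9.2 CPM (1.51 ± 0.13). Camera gave this list an adjusted p = 0.00241, and an adjusted p = 0.642 with an estimated correlation. Seed storage transcripts, markers of ungerminated seed, stood beside them: CRA1 was at 14.0 ± 8.3 CPM in WT, 10.6 ± 4.7 in bbx202122 and 29.7 ± 7.6 in hy5. Against WT, the list median was 0.81 in hy5 (camera adjusted p = 0.458) and -1.52 in bbx202122 (camera adjusted p = 0.0393). With an estimated correlation camera gave an adjusted p = 0.713 in hy5 and an adjusted p = 0.502 in bbx202122. Of 8 such genes 2 rose in hy5, adjusted over the list alone too (1 without WT replicate 1 or 2, 4 without WT replicate 3, 0 without hy5 replicate 1), and DESeq2 called neither. Of 13 jasmonate, wounding and pathogen genes 8 rose and 1 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.0151, adjusted p = 0.175 with an estimated correlation), with PR1 at 2.56 ± 0.28, LOX2 at 0.83 ± 0.08 and VSP1 at -1.57 ± 0.18.

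The iron deficiency regulator genes BHLH38 (-2.28 ± 0.17) and BHLH100 (-2.12 ± 0.17) and the iron transporter gene IRT1 (-1.29 ± 0.14) fell in hy5, while CSD2 (0.81 ± 0.09), a copper/zinc superoxide dismutase gene, and CCS (0.65 ± 0.06), the gene of its copper chaperone, rose. Of 19 iron and copper genes 12 fell and 3 rose (13 and 3 adjusted over the list alone; median -0.52, camera adjusted p = 0.000482; adjusted p = 0.296 with an estimated correlation). SULTR1;1, a sulfate transporter gene, fell by 2.61 ± 0.28 and NRT2.1, a nitrate transporter gene, by 3.03 ± 0.43 on the log2 scale. Of 10 nitrate and sulfate genes 4 fell and 2 rose (5 and 2 adjusted over the list alone), with a camera adjusted p = 0.265. Several of these genes act in roots, and root markers changed in the same whole-seedling libraries: 7 of 15 rose and 6 fell, among the latter EXPA18 (-2.09 ± 0.11), EXPA7 (-1.63 ± 0.13) and COBL9 (-1.48 ± 0.12). Of 9 cell cycle genes 7 fell, adjusted over the list alone too, such as CYCD3;1 (-0.50 ± 0.07).

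**Figure D2:**
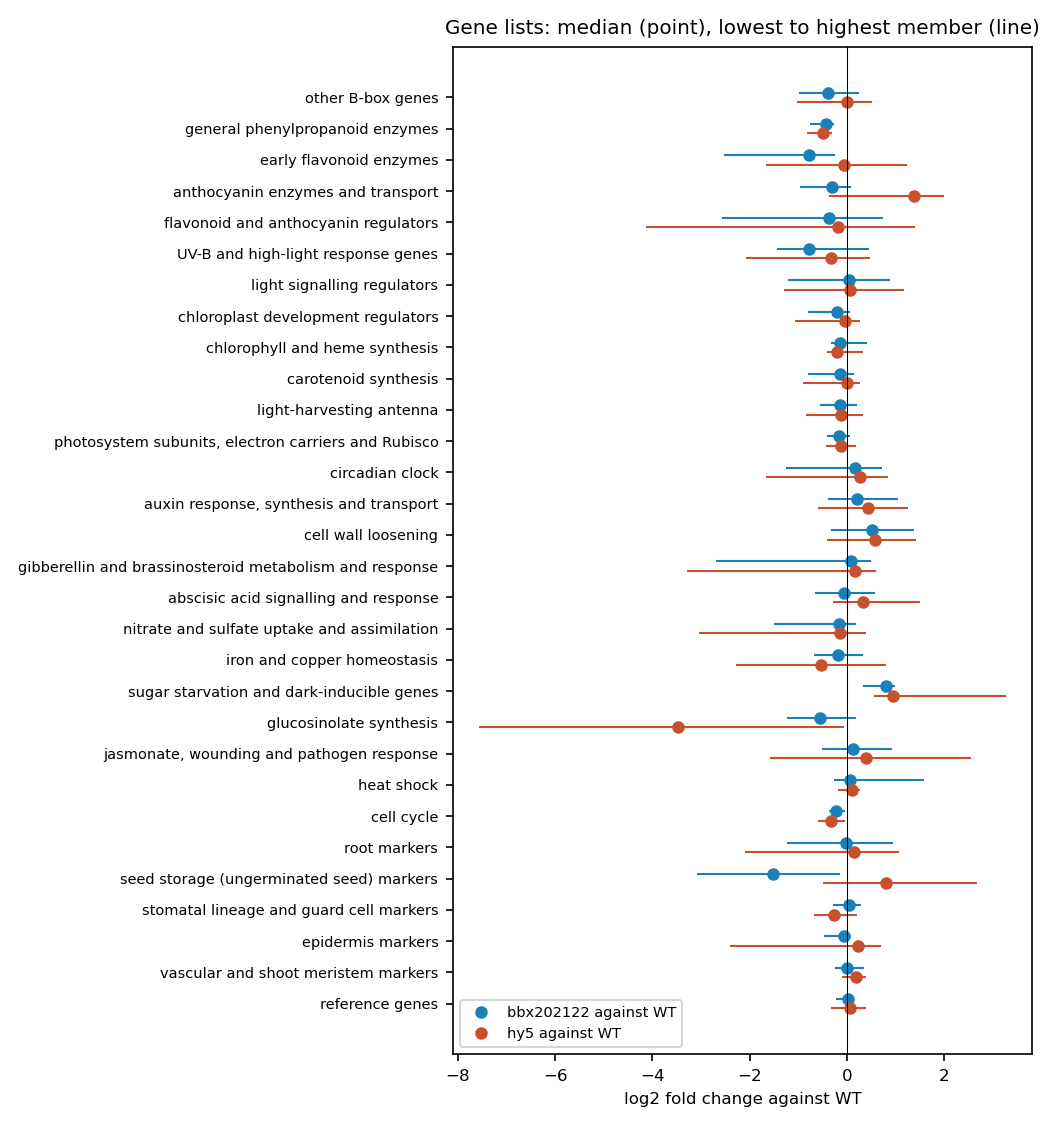
Log2 fold change against WT (horizontal axis) of the members of 30 gene lists in bbx202122 (blue) and hy5 (orange); points are list medians and lines run from the lowest to the highest member. The glucosinolate list stands furthest from 0 in hy5 (median -3.48; its lowest member, BCAT4, had 1 count in hy5), and the anthocyanin list lies at -0.30 in bbx202122 and 1.39 in hy5.

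A further 41 genes were near 0 in WT and bbx202122 and expressed in every hy5 library, a set singled out after its values were seen. AT1G40390 (chromosome 1, 15432576 to 15434674) had 0 counts in WT and 124 CPM in hy5, at least 2750-fold higher. AT1G23915, AT1G43815, AT4G08593 and AT4G04265 were at least 927-fold, 641-fold, 601-fold and 437-fold higher than in WT, although AT1G23915 shares 43.7% of its 50-base words with AT1G36085. Of the 41 genes 21 lie on chromosome 1 and 14 on chromosome 4, and 12 others were near 0 in hy5 alone, 5 of which share at least 50% of their 50-base words with another gene. By the same thresholds bbx202122 had 0 genes of either kind.

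**Figure D3:**
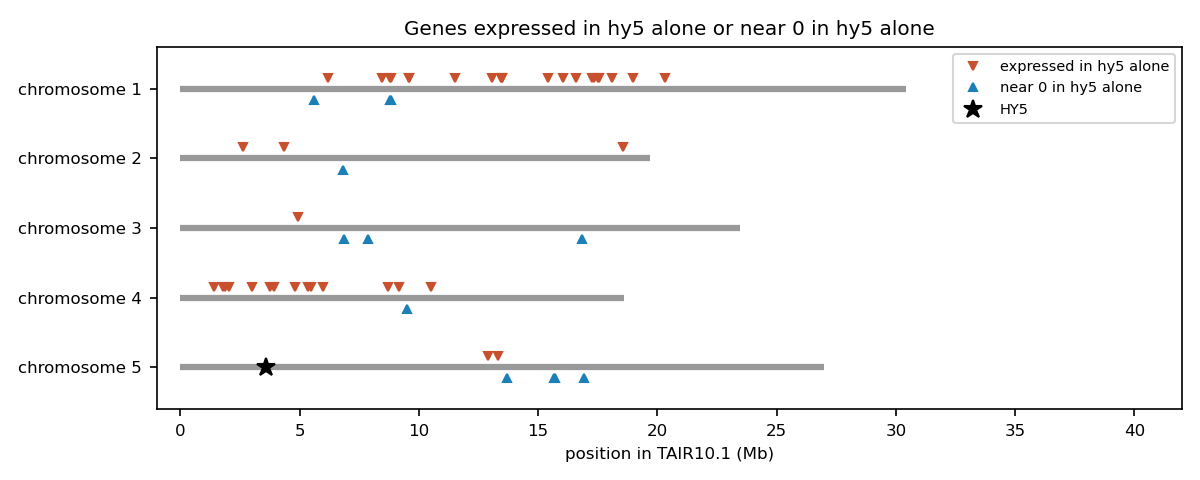
Positions in Mb of TAIR10.1 (horizontal axis) on the 5 chromosomes of the 41 genes expressed in hy5 alone (orange, under 0.1 CPM in WT and bbx202122 and at least 1 CPM in every hy5 library) and the 12 genes near 0 in hy5 alone (blue). None lies within 5 Mb of HY5 (star), and chromosomes 1 and 4 hold 21 and 14 of the 41.

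In hy5 8187 of 20751 genes were called, 4070 higher and 4117 lower (49.7% higher), and 1391 of them changed at least 2-fold, 394 higher and 997 lower. With library size as the only scaling 8172 genes were called and 38.2% were higher. Camera called 10 lists, 6 up and 4 down; 2 kept their call with an estimated correlation, cell wall loosening and glucosinolates, and the other 8 had an adjusted p of 0.175 to 0.642.

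The title of the study asks how far the B-box proteins and HY5 act together, and the mutants shared many changes. As HY5 and HYH transcripts fell in bbx202122 and BBX20 fell in hy5, the overlap alone cannot show that the proteins act together. Of the 3504 genes called in bbx202122, 2695 (76.9%) were called in the same direction in hy5, 1261 higher and 1434 lower, against 350.7 and 340.5 for independent lists. These were 32.9% of the calls in hy5. PIN5 (-3.09 ± 0.36 in bbx202122, -3.94 ± 0.42 in hy5) and MYB12 (-2.56 and -4.12) were among the largest shared decreases, and AT1G61750 (3.66 ± 0.34 and 5.20 ± 0.28) and WSD1 (3.56 ± 0.47 and 4.21 ± 0.44), a wax ester synthase gene, among the largest shared increases. AT3G02010 was at 0 counts in WT, at least 17.5-fold higher in bbx202122 and at least 50.3-fold higher in hy5, but all its 50-base words also occur in another gene, chiefly AK3, so its level is uncertain. The shift was larger in hy5 for 79.2% of the shared genes: shared increases had a median of 0.36 in bbx202122 and 0.50 in hy5, and shared decreases of -0.47 and -0.70. The direct comparison called 947 of the shared genes, 898 of them further from WT in hy5 and 49 in bbx202122. Opposite directions were called for 70 genes, against 691.3 for independent lists. Across the tested genes, which are not independent replicates, the log2 fold changes had a covariance of 0.123 and r = 0.448, and 73.6% had the same sign. The covariance depended on the processing, from 0.0531 with limma on log2(FPKM + 1) without a filter to 0.25 with DESeq2, also without a filter, and 0.311 with edgeR and no low-count filter. As both comparisons used the same 3 WT libraries, which are too few to be divided, part of this may come from WT: simulated unchanged mutants gave a covariance of 0.0167 ± 0.0011 (SD of 20 simulations), a mean r of 0.503, 66.6% with the same sign and at most 2 shared calls. Each simulated comparison called at most 5 genes, so the simulations cannot show how many of the 2695 shared calls come from WT. Without WT replicate 2 the shared genes were 1718.

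**Figure D4:**
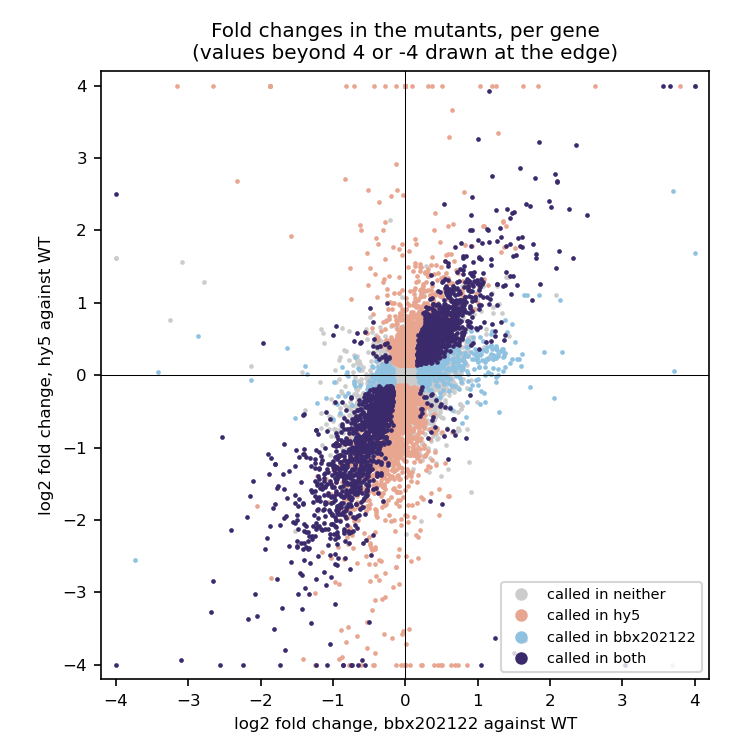
Log2 fold change of each tested gene in hy5 (vertical axis) against that in bbx202122 (horizontal axis), both against WT, coloured by call, with values beyond 4 or -4 drawn at the edge. Of the genes called in both, 2695 lie in the quadrants of equal direction and 70 in the others.

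The comparison of bbx202122 with hy5 tested the differences between the mutants themselves. The unstated background of hy5 limits this comparison in the same way. Glucosinolate genes were higher in bbx202122: MAM1 (4.56 ± 0.33), CYP83A1 (4.31 ± 0.29) and all 14 members of the list (14 adjusted over the list alone) rose, with a median of 2.73 that did not change with 2 members at their bounds. Camera gave an adjusted p = 2.46e-29, and an adjusted p = 0.0135 with an estimated correlation. Anthocyanin genes were lower: DFR (-2.31 ± 0.19), LDOX (-2.19 ± 0.22) and all 9 members fell, adjusted over the list alone too, with a median of -1.82 (camera adjusted p = 8.49e-13; adjusted p = 0.333 with an estimated correlation). Of 10 early flavonoid enzymes 8 were lower (9 adjusted over the list alone), led by F3'H (-1.76 ± 0.24), F3H (-1.68 ± 0.21) and CHS (-1.37 ± 0.13). TTL4 was also lower (-2.07 ± 0.09), as were BBX21 (-2.42 ± 0.07) and BBX22 (-3.47 ± 0.09). CSLA03 (AT1G23480), which fell in hy5 from 38.0 to 3.32 CPM and stood at 39.6 CPM in bbx202122, was higher by 3.57 ± 0.09, and AT5G26270 by 3.35 ± 0.13. AT4G16215 had 0 counts in bbx202122 and 108 CPM in hy5, at least 2460-fold lower in bbx202122.

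Of 19 iron and copper genes 12 were higher and 3 lower in bbx202122 (12 and 4 adjusted over the list alone), with BHLH38 at 1.74 ± 0.17 and IRT1 at 1.19 ± 0.14. Of 15 root markers 3 were higher and 3 lower in the same libraries, with EXPA18 at 0.87 ± 0.12. Of 14 abscisic acid genes 8 were lower, adjusted over the list alone too, with RD29A at -0.92 ± 0.12 and HAI1 at -0.86 ± 0.12. In the same libraries 5 of 8 seed storage genes were lower (CRA1 -1.47 ± 0.32). The median of the seed storage list was -2.44 (camera adjusted p = 0.021, and adjusted p = 0.441 with an estimated correlation). GPT2 (-2.26 ± 0.19) and BXL1 (-0.67 ± 0.10) were lower, as were 11 of 32 auxin genes, with 1 higher (12 and 1 adjusted over the list alone; 7 called without hy5 replicate 2), and 7 of 17 cell wall genes, with 1 higher (adjusted over the list alone too; 5 called without hy5 replicate 1). Chloroplast-encoded transcripts, read here in poly(A) libraries, were higher for 74 of 88 genes. In all 4773 genes were called, 2510 higher and 2263 lower (52.6% higher), and 668 changed at least 2-fold. With library size as the only scaling 5183 were called and 72.5% were higher. Camera called 10 lists, 2 up and 8 down; 1, glucosinolates, kept its call with an estimated correlation, and the other 9 had an adjusted p of 0.333 to 0.441. Fry, which tests whether the genes of a list moved on balance one way, called 17, 25 and 16 of 30 lists in bbx202122 against WT, hy5 against WT and bbx202122 against hy5. It tests a list against no change and not against the other genes, so its calls do not set a list apart from them. In hy5 against WT fry also called the reference genes (adjusted p = 0.048), which camera did not (adjusted p = 0.494).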

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

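The tests of gene-poor regions and of the sequence background of hy5 were chosen only after the result was seen.

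The mutants, compared with the same WT libraries, moved 70 genes in opposite directions. Of these, which were selected for opposite calls, the log2 fold change of bbx202122 against hy5 was 7.21 for QQS, an orphan gene linked to starch, which was at 0.949 CPM in WT and 7.82 CPM in bbx202122 and had 3 counts over the hy5 libraries, a ratio of 165 with a counting interval of 56.1 to 802. BBX21 differed by -2.42, lower in bbx202122 where it is mutated and higher in hy5. AT5G52790 differed by 1.52 (18.7, 30.1 and 10.5 CPM in WT, bbx202122 and hy5). GBSS1, a granule-bound starch synthase gene, differed by -1.17 (67.3, 41.2 and 93.0 CPM). CYP702A5 differed by 1.7 (3.80, 6.77 and 2.08 CPM).

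A set of 41 genes was expressed in hy5 alone. Reads shared between near-identical protein-coding genes do not account for most of the set. Of the 41, 4 (9.8%) had at least 50% of their 50-base words in another annotated protein-coding gene. Sequences outside annotated protein-coding genes, such as pseudogenes, were not searched, so reads shared with them stay open. A sequence background of the hy5 line that differs from WT stays open: 12 genes, with BCAT4 and CYP79F1 among them, were near 0 in hy5 alone against 0 in bbx202122, but this count was seen before the test was set and cannot count for it. Of the 12 genes 5, neither BCAT4 nor CYP79F1 among them, share at least 50% of their words with another gene, so their levels are uncertain. Loss of silencing cannot be told apart from it, as 18 of the 41 (43.9%) lay in gene-poor 1-Mb windows against 11.4% of 5381 other silent genes, a ratio of 3.86 (Fisher's exact p = 1.79e-07), while insertions and deletions between backgrounds may also gather there. Its test also asked that far fewer genes turn off than on (a ratio under 0.1), and 12 against 41 did not meet this. An effect of the loss of HY5 itself stays open and was not tested.

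Genes called in both mutants were searched for the G-box, which HY5 binds. Of the genes lower in both, 11.4% had CACGTG within 500 bp upstream, 1.14 times the mean of matched draws and inside their range of 8.5 to 11.5%. Of the genes higher in both, 9.3% had it, 1.0 times the matched mean. An enrichment of this motif thus did not mark either set, and other motifs or distances were not tested.

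Genes near the mutated loci were tested for linked differences that the crosses could have carried along. Within 100 annotated genes on either side of BBX20, BBX21 and BBX22, 94 of 514 tested genes (18.3%) were called in bbx202122 against 16.5% elsewhere, a ratio of 1.11. Around HY5, 56 of 168 (33.3%) were called in hy5 against 39.7% elsewhere, a ratio of 0.84. The share of called genes near the loci was thus close to or below that elsewhere. The windows hold too few tested genes to speak for the called genes as a whole. Longer linked segments and single genes near the loci stay open.

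Only 10 splits of 6 libraries into 3 and 3 exist per comparison, too few for a share under 0.05. The real split gave the most called genes in each, 1 of 10 splits. It gave 3504 for bbx202122 against WT, 8187 for hy5 against WT and 4773 for bbx202122 against hy5, and the highest other split gave 0 with edgeR in each (1346, 614 and 960 genes at an unadjusted p under 0.05).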

How the results depend on the processing

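The alternative without genes under a mean of 10 counts in any genotype was chosen only after seeing the data. The counts of called genes stayed within 1.5 times the reported ones under the other tools, scalings, filters and fits tried, from 2783 to 3523 for bbx202122 against WT, 6937 to 8417 for hy5 against WT, 3825 to 5183 for bbx202122 against hy5 and 2119 to 2715 for shared genes, with the exceptions given next. Asking for at least a 2-fold change left 382, 1391, 668 and 252 genes, fewer by construction, and an adjusted p under 0.01 in both mutants left 1359 shared genes. Leaving out single libraries gave 2236 (without WT replicate 2) to 3482 genes for bbx202122 against WT, 6649 to 8439 for hy5 against WT, 3332 to 4867 for bbx202122 against hy5 and 1718 to 2545 shared genes, with fewer libraries in each fit. The covariance of the fold changes was 0.126 to 0.159 without single libraries. It was 0.25 with DESeq2, which was run on all 24640 genes and so changed the tool and the filter together. With edgeR it was 0.311 with no low-count filter, 0.106 with the stricter filter and 0.117 with fits of 6 libraries. It was 0.0629 with limma on log2(FPKM + 1), 0.0921 with log2(FPKM + 0.1), 0.0531 with log2(FPKM + 1) and no filter, and 0.0921 without genes under a mean of 10 counts; the cause was not tested. No called value of a named gene changed sign in any of 22 alternatives. Of up to 501 called values of named genes, at most 58 lost their call in an alternative other than the 2-fold minimum, which ended 314. The difference in HY5 between bbx202122 and hy5 (-0.38 ± 0.13, adjusted p = 0.049) lost its call in 13. Deviations of same-numbered libraries correlated at 0.139, 0.072 and 0.037 between the mutants, above the at most 0.029 of their other pairs, and at -0.079 to -0.023 between WT and mutants. Replicate 1 of both mutants stood apart on the third principal component (20.96 and 15.99; 5.4% of the variance). As 1 of 9 same-numbered pairs exceeded 0.1 and 4 libraries correlated best with their own number, the numbers were not taken as pairs. A block for them gave 3143, 7884, 4445 and 2407 genes. Depth limits genes under about 0.132 CPM, 3 counts in a library.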

Other observations

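The organelle counts and the motif counts of genes called in a single mutant were chosen only after the result was seen. Organelle transcripts are measured here in poly(A) libraries, so their counts may depend on library preparation as well as on RNA levels. Which of these applies was not tested. Chloroplast-encoded genes had a median log2 fold change of 1.12 in bbx202122 and 0.27 in hy5, and mitochondrial genes of 0.43 and 0.16, with 6 and 3 of 41 called higher. Genes called in a single mutant are those not called in the other, and the mutants differed by the direct comparison for 375 of 739 called in bbx202122 alone and 2728 of 5422 called in hy5 alone. Of the genes lower in bbx202122 alone, 15.9% of 251 had an upstream G-box against 7.2 to 14.7% in matched draws, the others staying inside their draws: higher in bbx202122 alone 6.7% against 6.5 to 11.5%, lower in hy5 alone 9.8% against 8.8 to 11.1%, and higher in hy5 alone 11.1% against 9.0 to 11.2%.

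Some markers of organs and cell types changed with genotype. In hy5 camera called no list of this paragraph (adjusted p = 0.197 to 0.494), and 39.5% of all tested genes were called there. In bbx202122 camera called the root list alone of these, down (adjusted p = 0.0393, and adjusted p = 0.484 with an estimated correlation). Among 15 root markers, some genes of root hairs fell in both mutants, EXPA18 (-1.22 ± 0.10 in bbx202122, -2.09 ± 0.11 in hy5), EXPA7 (-0.96 ± 0.12 and -1.63 ± 0.13) and COBL9 (-0.85 ± 0.11 and -1.48 ± 0.12), while the root aquaporin genes TIP2;2 (0.78 ± 0.09 and 0.93 ± 0.09) and TIP2;3 (0.96 ± 0.12 and 1.08 ± 0.12) rose. In all 4 rose and 6 fell in bbx202122 and 7 rose and 6 fell in hy5, and their median (0.15) and mean (-0.38) in hy5 differed in sign. The stomatal lineage genes TMM (-0.58 ± 0.09) and SPCH (-0.47 ± 0.12) fell in hy5, where 4 of 8 such genes fell and 1 rose (3 called without hy5 replicate 2). In bbx202122 1 rose and 1 fell, and called members were 1 without WT replicate 1 or 3 or bbx202122 replicate 2 and 0 without bbx202122 replicate 1. Of 7 epidermis markers 5 rose and 2 fell in hy5 (median 0.24, mean -0.13), with LTP1 at 0.70 ± 0.07 and GL1 at -2.41 ± 0.40. In bbx202122 edgeR and DESeq2 called 0 of them, with 0 at an unadjusted p under 0.05. Of 9 vascular and meristem markers 4 rose in hy5, with IRX1 at 0.39 ± 0.10 (called members were 1 without WT replicate 1 or hy5 replicate 2, 2 without WT replicate 2 or hy5 replicate 3, and 1 with library size as the only scaling). In bbx202122 edgeR and DESeq2 called 0 of these, with 2 at an unadjusted p under 0.05. Of 11 reference genes 5 rose and 2 fell in hy5, with ACT7 at 0.40 ± 0.06, UBQ10 at 0.32 ± 0.07 and EF1A at -0.33 ± 0.07.

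Further lists held few calls in bbx202122, and most of these counts rest on single libraries. Adjusted over the list alone, calls in bbx202122 were 1 higher for abscisic acid, 1 higher and 4 lower for nitrate and sulfate, 2 higher and 4 lower for iron and copper, and 1 higher and 1 lower for heat shock genes; for the other lists here, apart from cell cycle genes, both counts were the same. Of 8 seed storage genes 1 fell (2 without WT replicate 2, 3 without bbx202122 replicate 3, and 0 without WT replicate 3 or bbx202122 replicates 1 or 2). The median of the seed storage list was -1.52. Of 14 abscisic acid genes 2 rose, among them RD29A (0.59 ± 0.13); 1 was called without any single WT library, bbx202122 replicates 1 or 2 or hy5 replicate 3, and 4 without bbx202122 replicate 3. Of 13 jasmonate, wounding and pathogen genes 4 rose (2 without WT replicate 2), with TCH3 at 0.92 ± 0.07. Of 10 nitrate and sulfate genes 4 fell (2 without WT replicate 2), with APR2 at -0.29 ± 0.05. Of 19 iron and copper genes 2 rose and 3 fell (2 called without WT replicate 2 or bbx202122 replicate 2), with CCS at 0.33 ± 0.06. Of 9 cell cycle genes 1 fell, KNOLLE (-0.31 ± 0.06), and 5 fell adjusted over the list alone; 3 were called without hy5 replicate 1 and 2 without WT replicate 3, any single bbx202122 library or hy5 replicate 3. Of 7 heat shock genes HSP17.6A rose in bbx202122 (1.59 ± 0.38), a call lost without WT replicate 1 or 2, while 2 were called without bbx202122 replicate 1 or 3. In hy5 edgeR and DESeq2 called 0 heat shock genes, with 0 at an unadjusted p under 0.05. Of 11 reference genes 2 fell in bbx202122; 0 were called without WT replicates 2 or 3, bbx202122 replicates 1 or 2 or hy5 replicate 2, and 1 without bbx202122 replicate 3 or hy5 replicates 1 or 3.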
